A study of Mus musculus with 9 samples.

How the data were processed

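Mature microRNAs (miRNAs, short RNAs that repress messenger RNAs) were measured by small-RNA sequencing in 9 liver libraries from wild-type C57 BL6 mice aged 8 weeks. The 3 groups held 3 libraries each. Control animals received saline, APAP animals received 500 mg/kg acetaminophen (APAP) into the peritoneum, and dmPGE2+APAP animals received 300 µg/kg dmPGE2, a methylated analog of prostaglandin E2, 1 h before the same dose of APAP. All livers were collected 6 h after APAP. The labels give no vehicle for dmPGE2 and no group with dmPGE2 alone, so its effect was measured only on top of APAP. They do not state that each library is a separate animal, so p-values measure the spread between these libraries, which may be technical.

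The deposited read counts are whole numbers per mature miRNA, per the file headers, in 1 table of 946 rows. Reads were mapped with Bowtie to mm10, per the submitters' processing notes. The aligner's version, the counting tool, the miRNA annotation and the strand setting are not given in the sources used here. The deposited TPM values, per the file headers, equal each count over the library's total times a constant, with no length term. They served for 1 alternative only. Column names of the APAP and dmPGE2+APAP libraries match the labels, and the remaining columns, which carry another prefix, were taken as Control because no other group was left. The number of value columns not used was 0.

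Total reads per library were 7590735, 9739009 and 10483460 in Control, 6603745, 7563788 and 3523998 in APAP, and 6994952, 1038799 and 4733882 in dmPGE2+APAP. At the shallowest depth a miRNA at 10 CPM (reads scaled to a common library total) holds about as many reads as its CPM value, so low miRNAs there carry wide counting error. PCR copies are not independent molecules, so counting intervals cover counting error only.

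Counts were tested in R 4.3.3 with edgeR 4.0.16, using TMM library scaling, the filterByExpr filter (minimum count 10, minimum total 15) and the robust quasi-likelihood test. All 9 libraries entered 1 fit with 3 group means. The 360 miRNAs that passed the filter were tested in 3 comparisons, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Log2 fold changes are given with a standard error (SE) derived from the F statistic, and CPM values are scaled by TMM.

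The 21 miRNA lists covered liver cell types, other tissues, response pathways and families, with 183 distinct members, of which 175 were in the table and 124 were tested. The 17 lists with at least 3 tested members were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01 between members. Camera with an estimated correlation and fry were run beside it. Fry's p tests whether members move, on balance, one way, and does not compare a list with other miRNAs. Counts of members called when p was adjusted over the list alone are given beside the lists.

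Named miRNAs followed a fixed rule per comparison. It took up to 10 rises and 10 falls past the threshold with a mean of at least 10 CPM over both groups and no overlap between replicates. Where fewer than 10 passed, it added the 10 with the lowest unadjusted p at that abundance, said not to pass. It further took up to 4 examples per list (called members, or otherwise the 2 most abundant), the 10 most abundant miRNAs, and up to 10 opposite calls. Any name outside the rule is marked as chosen after its values were seen.

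Several rows count the same reads. A pair of rows was taken to share reads when the counts differed by at most 5% or 2 reads in every library, with a log2 correlation above 0.99 and at least 100 reads. These settings were chosen after seeing the data. They found 13 pairs, and in 12 of them the hairpin genes overlap in the reference, as for miR-122-5p with miR-122b-3p and miR-486a-5p with miR-486b-3p. Without a stated strand setting such antisense partners cannot be told apart. The rows of miR-486a-3p and miR-486a-5p, and those of miR-129b-3p and miR-129-5p, differed by few reads without meeting the criterion. Hairpin coordinates are from RefSeq on GRCm38.p6, the same build as mm10, are 1-based, and were found for 83 of the 83 miRNAs looked up.

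The scripts were tested on 10 simulated data sets with the real abundances and library sizes and 200 miRNAs changed between APAP and Control, about 358 of the miRNAs being tested in each. Of the changed miRNAs that passed the filter, the test recovered 93.5% of 4-fold and 48.9% of 2-fold changes, with 0 of the wrong sign. Changed miRNAs that the filter removed are left out of these shares. With so many miRNAs changed, the Benjamini-Hochberg cutoff is looser than with few, so these shares may overstate recovery where few change. Of the test's calls, 5.26% were false. A 2-fold shift of the miR-30 list was called in 10 of 10 simulated sets with either correlation. Each miRNA was drawn independently there, so these sets do not show how either version performs when list members are correlated.

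Alternatives were other scaling (RLE, upper quartile, library totals, leaving out the 10 most abundant miRNAs), other filters, DESeq2 1.42.0, limma-voom, limma on log2(TPM + 1), fits of only the 2 groups compared, the replicate number as a block, and each library left out in turn. Collapsing rows that share reads and thinning every library to 1038799 reads were added after seeing the data.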

Results

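The study asked how acetaminophen, which injures the liver at high dose, changed liver miRNAs after 6 h, and how a prior dose of dmPGE2 altered that response. Small RNA was sequenced in 9 liver libraries, 3 per group, to between 1038799 and 10483460 reads. Control libraries were deeper (9271070 ± 1502060 reads, SD, n = 3) than APAP (5897180 ± 2110550) and dmPGE2+APAP libraries (4255880 ± 3006710). An exact two-sided permutation test gave p = 0.1 for either difference from Control, the smallest value that 3 against 3 libraries allow.

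The row of miR-122-5p, the main hepatocyte miRNA, held 19.6% ± 4.32 (SD, n = 3) of reads in Control, 19.0% ± 0.359 in APAP and 20.2% ± 1.24 in dmPGE2+APAP. The row of miR-122b-3p, whose hairpin overlaps it, holds nearly the same reads, and with such rows counted once the shares were 24.8%, 23.6% and 25.4%. Next in mean abundance over all libraries were miR-21a-5p at 192003 CPM (above miR-122-5p in the APAP group mean), miR-148a-3p at 105739, miR-192-5p at 84853 and miR-143-3p at 32299, followed by miR-26a-5p, miR-30a-5p, let-7f-5p and miR-22-3p. The 10 most abundant rows held 88.8% ± 1.15 of Control reads, 87.1% ± 1.11 of APAP reads and 87.3% ± 1.27 of dmPGE2+APAP reads. Exact two-sided permutation tests of these shares gave p between 0.2 and 1.

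After APAP, 3 of 360 miRNAs were higher than in Control. The passenger strand of the miR-21 hairpin, miR-21a-3p (chromosome 11, 86584067 to 86584158), rose from 7.0 ± 4.69 to 29.5 ± 7.13 CPM (SD, n = 3), a log2 change of 2.09 (SE 0.44) with an adjusted p of 0.0284 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Its abundant partner strand miR-21a-5p had a log2 value of -0.19 (SE 0.21), which became 0.06 with library totals, and did not pass. The other called miRNAs lay under 10 CPM and were chosen after their values were seen. miR-503-5p (chromosome X, 53053984 to 53054054), of a cluster tied to cell-cycle control, rose from 1.68 ± 0.27 to 6.54 ± 1.61 CPM, a log2 change of 1.94 (SE 0.36), with edgeR's adjusted p at 0.0224. miR-6481 (chromosome 3, 99199344 to 99199453) had 3 reads in all Control libraries and 93 in all APAP libraries, a depth-scaled ratio of 42.1 with an exact 95% counting interval of 14.0 to 208, and edgeR's adjusted p was 0.0284.

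With edgeR 0 miRNAs were lower after APAP, while 12 were lower and 23 higher at an unadjusted p under 0.05. DESeq2 called 11 higher and 2 lower, and limma-voom called 2 higher and 0 lower. The call of miR-21a-3p was lost without Control replicate 2, APAP replicate 1 or APAP replicate 3, with edgeR's adjusted p then between 0.0604 and 0.112, at a mean of at least 10 CPM (0.0777) and when only these 2 groups were fitted (0.0602). Leaving out any Control library, APAP replicate 1 or APAP replicate 3 ended the calls of both miR-503-5p (0.0518 to 0.124) and miR-6481 (0.0518 to 0.125), and the latter was also lost without dmPGE2+APAP replicate 2 (0.0704) and with limma-voom (0.0888). With the replicate number as a block every call was lost (edgeR adjusted p 0.0809 for miR-21a-3p, and 0.0540 for miR-503-5p and for miR-6481). Thinning to equal depth also ended the call of miR-21a-3p (0.0885).

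miRNAs of red blood cells were higher as a group after APAP. All 6 tested rows of the erythroid list had values above 0, with a median log2 change of 1.17. The adjusted camera p was 1.43e-07 with the preset correlation of 0.01, which treats members as nearly independent. The estimated correlation between them was 0.699, and with it camera's adjusted p = 0.227, so the list was not called. Fry did not call it either (FDR 0.0705). miR-451a, which matures in red-cell precursors without Dicer (chromosome 11, 78073170 to 78073241), had 409 ± 34.0 CPM in Control and 800.4 ± 323 in APAP (log2 0.97, SE 0.24), and miR-486a-3p had 48.7 ± 12.9 and 109 ± 44.9 (log2 1.17, SE 0.29). Neither passed over all miRNAs, at an edgeR adjusted p of 0.0571 each. Of 22 alternatives, miR-451a passed in 10 and miR-486a-3p in 11, for example with DESeq2 (0.0103 and 0.00663) and without APAP replicate 2 (0.0326 and 0.00823). Over the alternatives their log2 values ranged from 0.61 to 1.23 and from 0.82 to 1.47, with an edgeR or other adjusted p of up to 0.3985 for each. Adjusted over the list alone, 6 of 6 rows passed, but 3 of them count the miR-486 reads.

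The myeloid list, of neutrophil and macrophage miRNAs, was also higher (4 of 4 values above 0, median log2 0.59, adjusted camera p 0.0194), as miR-223-3p showed at 13.5 ± 2.54 CPM in Control and 27.7 ± 8.01 in APAP (log2 1.03, SE 0.31) and miR-142a-5p at log2 0.41 (SE 0.31). With an estimated correlation its adjusted p = 0.227, and it was lost without Control replicate 2 (0.0769) or Control replicate 3 (0.0528), at a mean of at least 10 CPM (0.0918) and after thinning to equal depth (0.196). Adjusted over the list alone, 1 member was called.

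Both the liver-enriched list and the miR-30 family were lower after APAP. The liver-enriched list had 9 of 10 values below 0, a median log2 of -0.29 and an adjusted camera p of 0.0205 (0.227 with an estimated correlation), with miR-122-5p at -0.34 (SE 0.23) and miR-148a-3p at -0.41 (SE 0.21). In miR-30, 10 of 11 values lay below 0, with a median of -0.41 and an adjusted camera p of 0.0105 (0.227 with an estimated correlation), miR-30a-5p at -0.44 (SE 0.22) and miR-30d-5p at -0.45 (SE 0.24). Scaling to library totals, which moved the median of all miRNAs by 0.25, gave medians of -0.04 and -0.16 and an adjusted p of 0.0835 for the liver-enriched list. That list was also lost without Control replicate 3 (0.0729) or APAP replicate 3 (0.0582) and when only these 2 groups were fitted (0.0503), and miR-30 without APAP replicate 3 (0.0553) and after thinning (0.0520). Adjusted over the list alone, miR-148a-5p alone was called in the former and 0 members in the latter.

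Fry called 0 lists after APAP (lowest FDR 0.0705). The other 13 lists tested with camera did not pass in this comparison, with adjusted p of 0.17 or more. Their median log2 values were 0.17 for endothelial, -0.01 for stellate and mesenchymal, 0.00 for cholangiocyte and epithelial, -0.96 for muscle, 0.33 for neuronal, 0.15 for inflammation, 0.43 for cAMP and CREB responsive, 0.08 for miR-17-92 and paralog clusters, -0.17 for liver regeneration, -0.13 for let-7, 0.03 for miR-29, -0.12 for metabolic regulators and -0.25 for the Dlk1-Dio3 cluster. Median and mean differed in sign for liver regeneration (mean 0.15, through miR-21a-3p), miR-29 (mean -0.10), cholangiocyte and epithelial (mean -0.04) and metabolic regulators (mean 0.11), and with library totals the medians of liver regeneration, let-7, metabolic regulators, the Dlk1-Dio3 cluster and the stellate and mesenchymal list became 0.06, 0.11, 0.09, 0.01 and 0.22. The muscle list passed in 4 of 17 alternatives: with library totals (0.0323) and without Control replicate 3 (median -1.32, adjusted p 0.00915), APAP replicate 3 (-1.16, 0.0121) or dmPGE2+APAP replicate 3 (-0.95, 0.0474). Over all 17 its median ranged from -1.32 to -0.20, with an adjusted camera p of up to 0.559. Its member miR-499-5p held 101, 42.3 and 12.7 CPM in Control replicates 1, 2 and 3. Leaving out Control replicate 3 thus removed the lowest of these values. The Dlk1-Dio3 cluster passed without Control replicate 1 (-0.34, 0.0428) or APAP replicate 3 (-0.47, 0.00516), and miR-17-92 without APAP replicate 3 (0.28, 0.0387). Adjusted over the list alone, 1 member was called in each of neuronal (miR-128-3p), inflammation and liver regeneration (both miR-21a-3p), and 0 in the other 10. Too few members were tested in the lymphoid, pancreas, p53-responsive and hypoxia lists, where values included miR-150-5p at 0.06, miR-375-3p at 0.08, miR-34a-5p at 0.14 and miR-210-3p at 0.09.

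Among miRNAs with the lowest unadjusted p that did not pass, miR-23a-3p had 182 ± 48.3 CPM in Control and 431 ± 146 in APAP (log2 1.24, SE 0.35), miR-652-3p had a log2 value of 1.07 (SE 0.30), and miR-128-3p had 0.78 (SE 0.23). Lower values were measured for miR-3470b (log2 -1.06, SE 0.29) and miR-148a-5p (log2 -0.74, SE 0.21). edgeR's adjusted p lay between 0.0969 and 0.111 for these, and of 22 alternatives they passed in 6, 2, 3, 2 and 1, in this order.

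**Figure D1:**
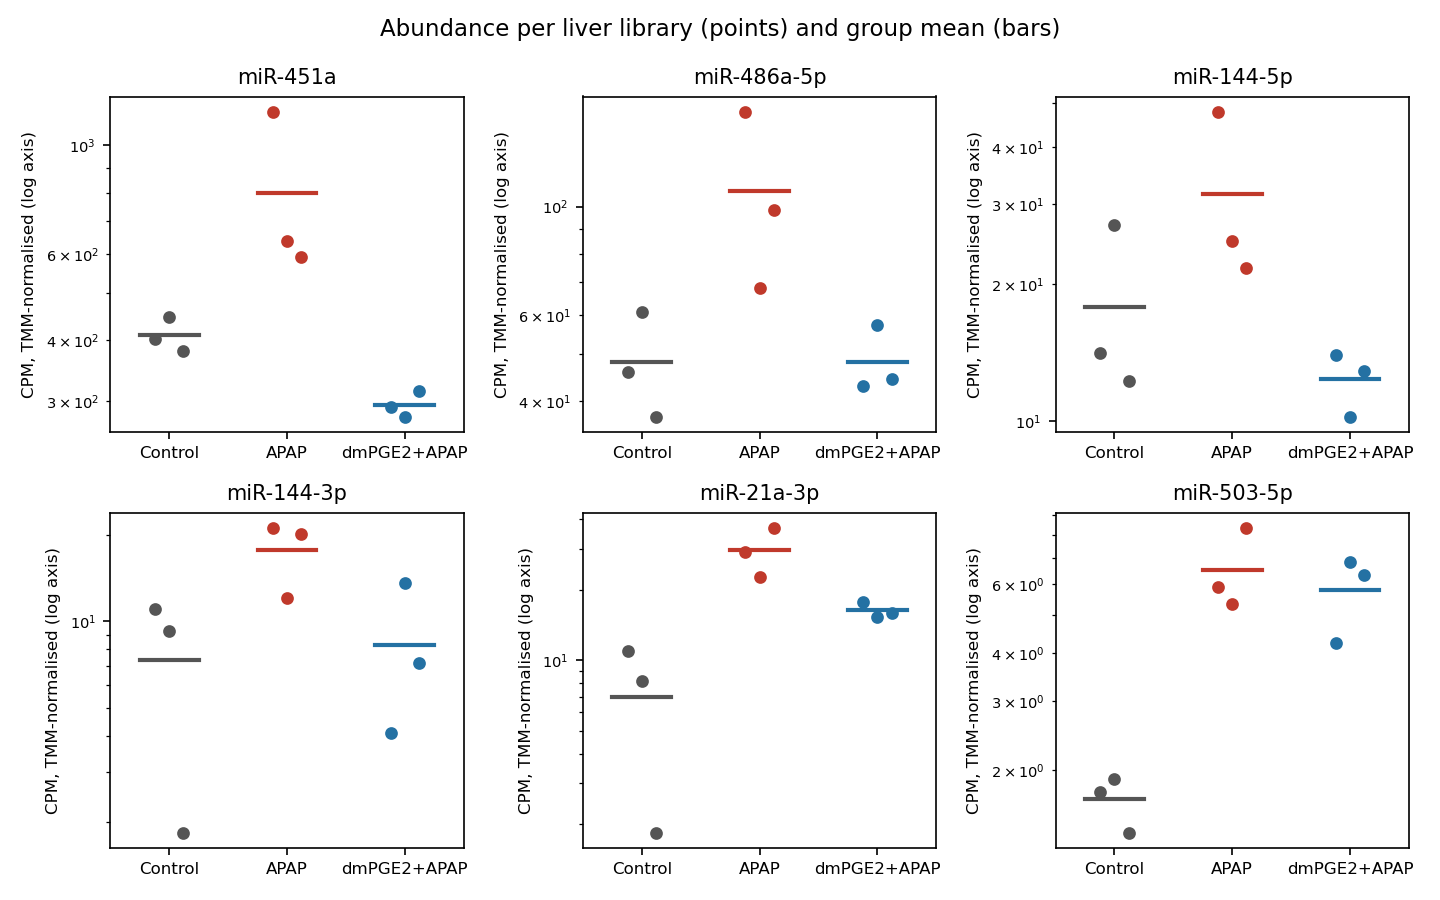
Abundance of 6 miRNAs in each of the 9 libraries, in TMM-normalised CPM on a log axis, with points for libraries and bars for group means. For miR-451a the APAP libraries lie between 590.2 and 1172 CPM, Control between 379 and 446, and dmPGE2+APAP between 279 and 314.

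With dmPGE2 before APAP, 1 of 360 miRNAs was lower than with APAP alone. That miRNA was miR-451a, at 800.4 ± 323 CPM in APAP and 295 ± 18 in dmPGE2+APAP (SD, n = 3), a log2 change of -1.44 (SE 0.25) with an adjusted p of 0.00993 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. All 3 dmPGE2+APAP libraries lay below all 3 APAP libraries. The call was lost without APAP replicate 1 (log2 -1.05, edgeR adjusted p 0.0620) or dmPGE2+APAP replicate 2 (log2 -1.35, 0.0568), and when only these 2 groups were fitted (0.0964). In the main test 0 miRNAs were higher, with 9 higher and 14 lower at an unadjusted p under 0.05. DESeq2 called 3 higher and 5 lower, and limma-voom called 1 lower.

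Red-cell miRNAs were lower as a group with dmPGE2. All 6 tested rows of the erythroid list lay below 0 (median log2 -1.23, adjusted camera p 4.21e-09 with the preset correlation of 0.01). The estimated correlation between its members was 0.699, and with it camera's adjusted p = 0.174. miR-144-5p, made from a hairpin next to that of miR-451a (chromosome 11, 78073005 to 78073070), had 31.5 ± 14.3 CPM in APAP and 12.4 ± 1.94 in dmPGE2+APAP (log2 -1.32, SE 0.36), and miR-486a-5p had 108 ± 44.8 and 48.1 ± 7.78 (log2 -1.18, SE 0.29). Neither passed over all miRNAs (edgeR adjusted p 0.122 and 0.0912, passing in 2 and 3 of 22 alternatives). When adjusted over the list alone 6 of 6 rows passed, but several of these rows count the same miR-486 reads.

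The myeloid list was lower too, with 4 of 4 values below 0, a median log2 of -0.75 and an adjusted camera p of 0.0106, although adjusted p = 0.174 with an estimated correlation. miR-223-3p had 27.7 ± 8.01 CPM in APAP and 13.7 ± 5.49 in dmPGE2+APAP (log2 -0.93, SE 0.32). This list was lost without APAP replicate 3 (0.0895) or dmPGE2+APAP replicate 1 (0.0524) and after thinning (0.172). The miR-17-92 and paralog clusters, which promote proliferation, had 11 of 11 values below 0 (median log2 -0.31, adjusted camera p 0.00108, but 0.174 with an estimated correlation), with miR-93-5p at -0.30 (SE 0.30) and miR-25-3p at -0.16 (SE 0.19). The lowest member stood at -2.97, and the mean of the list was -0.64. After thinning the clusters had an adjusted p of 0.0510. Adjusted over the list alone, 1 myeloid and 0 miR-17-92 members were called.

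Fry called 0 lists with dmPGE2 (lowest FDR 0.154). The other 14 lists tested did not pass (adjusted camera p of 0.15 or more). Their median log2 values were 0.07 for liver-enriched, 0.16 for endothelial, 0.12 for stellate and mesenchymal, 0.18 for cholangiocyte and epithelial, -0.43 for muscle, 0.21 for neuronal, -0.09 for inflammation, 0.13 for cAMP and CREB responsive, -0.24 for liver regeneration, -0.21 for let-7, 0.03 for miR-29, 0.02 for miR-30 (mean -0.02), -0.17 for metabolic regulators and 0.19 for the Dlk1-Dio3 cluster. With a library left out, the Dlk1-Dio3 cluster passed without APAP replicate 3 (0.53, adjusted p 0.0330) or dmPGE2+APAP replicate 2 (0.29, 0.00663), and let-7 without APAP replicate 3 (-0.26, 0.0400). miR-21a-3p stood at -0.83 (SE 0.43) and miR-210-3p, of the hypoxia list, at -0.73 (SE 0.37). No list of these had a called member (0 each) when p was adjusted over the list alone. Of miRNAs that did not pass, miR-3470b had the lowest p, with 7.34 ± 1.19 CPM in APAP and 18.5 ± 4.81 in dmPGE2+APAP (log2 1.29, SE 0.30, edgeR adjusted p 0.0912, passing in 3 of 22 alternatives), followed among others by miR-466i-5p (log2 0.96, SE 0.31) and miR-690 (log2 1.02, SE 0.42).

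**Figure D2:**
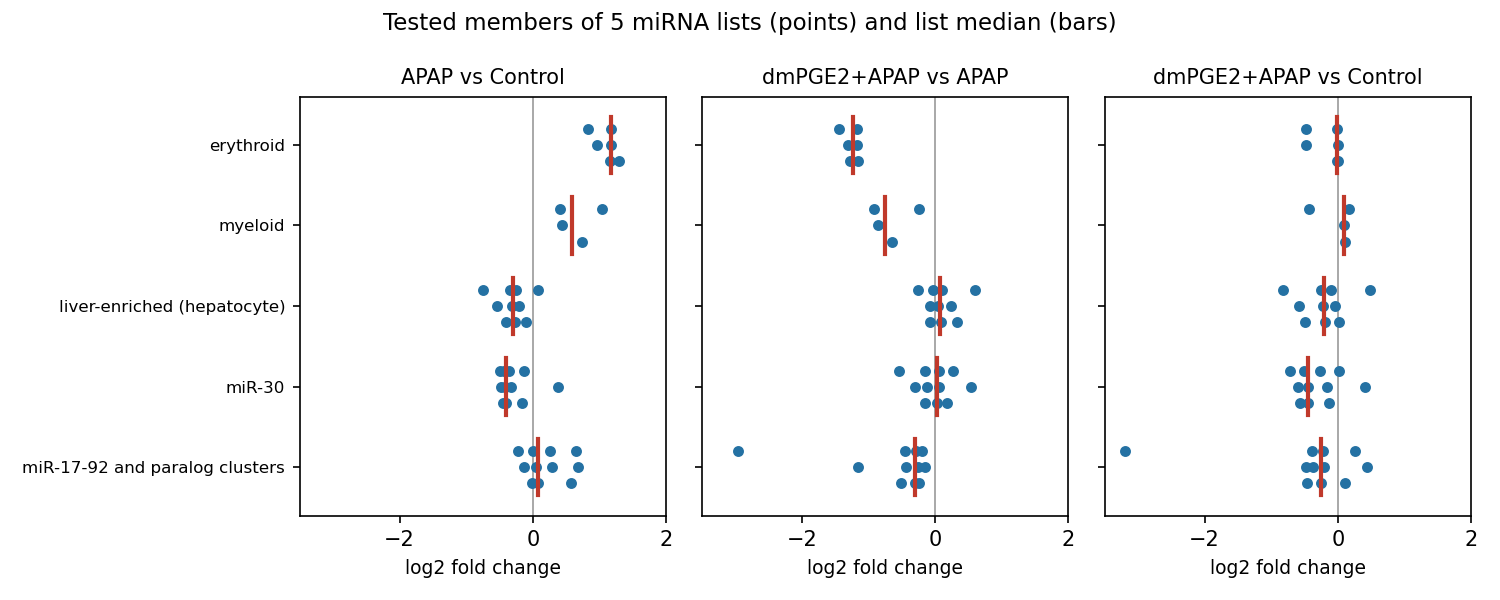
Log2 fold changes of the tested members of 5 miRNA lists (points) and the list medians (bars) in the 3 comparisons. Erythroid medians are 1.17 for APAP vs Control, -1.23 for dmPGE2+APAP vs APAP and -0.01 for dmPGE2+APAP vs Control.

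Livers given both drugs differed from Control in 1 miRNA. miR-6481 had 221 reads in dmPGE2+APAP against 3 in Control, a depth-scaled ratio of 140.4 with an exact 95% counting interval of 47.4 to 686, and its adjusted p was 0.00203 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The 3 dmPGE2+APAP libraries held 4.67, 24.7 and 32.5 CPM. edgeR called 0 lower, with 20 higher and 18 lower at an unadjusted p under 0.05. DESeq2 called 2 higher and 0 lower, and limma-voom called 0, with miR-6481 at an adjusted p of 0.112.

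Of the 17 lists tested, camera called 0 in this comparison, with 5 at an unadjusted p under 0.05, and an estimated correlation or fry also gave 0 (lowest fry FDR 0.242). The erythroid list had a median log2 of -0.01, with miR-451a at -0.47 (SE 0.24), and the myeloid list had 0.10 (mean -0.01). Medians of the others were -0.20 for liver-enriched, 0.25 for endothelial, 0.03 for stellate and mesenchymal, 0.15 for cholangiocyte and epithelial, -1.13 for muscle, 0.54 for neuronal, -0.01 for inflammation (mean 0.33), 0.56 for cAMP and CREB responsive, -0.25 for miR-17-92, -0.38 for liver regeneration, -0.28 for let-7, 0.09 for miR-29 (mean -0.05), -0.44 for miR-30, 0.00 for metabolic regulators (mean 0.03) and 0.02 for the Dlk1-Dio3 cluster (mean -0.01). With library totals, which moved the median of all miRNAs by 0.23 here, the medians of the liver-enriched, erythroid, inflammation and metabolic lists became 0.03, 0.27, 0.18 and 0.24. The muscle list passed in 5 of 17 alternatives: with library totals (adjusted p 0.0458) and without Control replicate 3 (median -1.48, 0.0105), APAP replicate 1 (-1.37, 0.0348), dmPGE2+APAP replicate 2 (-1.15, 0.0432) or dmPGE2+APAP replicate 3 (-0.92, 0.0151). Over all 17 its median ranged from -1.60 to -0.34, with an adjusted camera p of up to 0.597. When p was adjusted over the list alone, 1 member was called lower in each of liver-enriched, muscle and miR-17-92. The lowest miR-17-92 member stood at -3.19, with a list mean of -0.43. Below the threshold, the lowest p-values belonged to miR-148a-5p (log2 -0.83, SE 0.21, edgeR adjusted p 0.141), miR-365-3p (log2 -1.25, SE 0.36), miR-466i-5p (log2 1.05, SE 0.31) and miR-652-3p (log2 1.03, SE 0.31). miR-499-5p, a heart and muscle miRNA, had 52.1 ± 45.1 CPM in Control and 4.82 ± 4.69 in dmPGE2+APAP (log2 -3.28, SE 0.96), and it varied from 12.7 to 101 CPM within Control.

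The next question was whether dmPGE2 reversed what APAP changed. With edgeR 0 miRNAs were called in both comparisons with opposite sign, where simulated unchanged groups gave a mean of 0.03 and independent lists 0.00833 or fewer per direction. DESeq2 gave 5. At an adjusted p of 0.1 there were 5 rows, miR-451a, miR-486a-5p, miR-486a-3p, miR-486b-3p and miR-3470b, chosen after their values were seen. The miR-486 rows among them count nearly the same reads, so the 5 rows are fewer separate miRNAs. The simulated mean of 0.03 is for the edgeR count at the main threshold, so it is no reference for either count of 5. Over all 360 miRNAs the fold changes had a covariance of -0.0531, and -0.0823 without miR-6481, against a simulated mean of -0.0779 (range -0.126 to -0.0414) that the shared APAP libraries give with no effect. Both comparisons with Control shared 1 call, miR-6481 (simulated mean 0.02, independent lists 0.00833). The libraries are too few to split the shared Control group, so part of the excess over independent lists can come from it. The simulated groups share Control as well, and at most 1 shared call occurred in them. The covariance of both comparisons with Control was 0.266, and 0.162 without miR-6481, against a simulated 0.0713 (range 0.0381 to 0.116).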

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

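Tests of the explanations below were chosen after the results were seen, while the counts over other groupings of the libraries were planned. The change against Control differed between livers given APAP with and without dmPGE2, by the test of dmPGE2+APAP against APAP itself, for miR-451a (log2 -1.44), the erythroid list (median -1.23), the myeloid list (-0.75) and the miR-17-92 and paralog clusters (-0.31). The 3 list differences were not called with an estimated correlation.

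The red-cell miRNAs were higher with APAP (median log2 1.17) and stood at a median of -0.01 from Control with dmPGE2 (mean -0.16, miR-451a at -0.47). The rise with APAP and the fall with dmPGE2 rest on the same APAP libraries. Such sharing gives opposite signs even with no effect, so they are not independent results. A lower share of hepatocyte RNA would lift other cell types alike if APAP left those cells unchanged, which was not tested. The change in the mean of the 4 erythroid miRNAs that share no reads was set against that of 12 endothelial and mesenchymal ones. The first change minus the second was 1.10 ± 0.48 (log2, SE, n = 3) after APAP and -1.36 ± 0.29 with dmPGE2. The exact two-sided permutation p was 0.1 for each, the smallest possible, so a changed hepatocyte share is not excluded. With each read counted in 1 row, the mean of these 4 erythroid miRNAs, only 1 of them for the miR-486 reads, moved by 1.09 ± 0.41 and -1.22 ± 0.30 (SE, n = 3, exact permutation p = 0.1 each). The measured changes were thus not confined to rows that repeat reads. The other 3 are miR-451a and both arms of miR-144 from adjacent hairpins, so they are not independent of each other. A different amount of red-cell RNA in the tissue, for example blood left in the sample or bleeding into it, and changed expression by treatment both stay open. Neither was tested, and the amount of blood in each liver was not measured here.

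Groupings of the 6 libraries in each comparison number 10, the real one included, too few for a share under 0.05. APAP against Control gave 3 calls and at most 0 in the other groupings, reached in 1 of 10. For dmPGE2+APAP against APAP it was 1 call against 0 (1 of 10), and for dmPGE2+APAP against Control 1 against 0 (1 of 10). Simulated unchanged groups gave at least 1 call in 12, 13 and 12 of 100 draws of these comparisons, with at most 2, 3 and 3. List counts were reached more often: 4 of 10 groupings had at least the 4 lists of APAP against Control, with up to 5 in another grouping, and 2 of 10 had at least the 3 lists of dmPGE2+APAP against APAP, with up to 3. The 0 lists of dmPGE2+APAP against Control are reached by any grouping (10 of 10, with up to 3), which tests nothing. For the call shared by both comparisons with Control, 1 of 100 drawn groupings of the 9 libraries, the real one, gave 1, and the others 0. Such a count was thus rare over groupings, but chance is not excluded, since simulated unchanged groups also reached 1 shared call (mean 0.02). The shared count rests on miR-6481 alone, with 3 reads in Control. It became 0 without any one of the Control libraries, APAP replicate 1, APAP replicate 3 or dmPGE2+APAP replicate 2, and with the replicate block. At a mean of at least 10 CPM it was also 0, as miR-6481 was not tested there.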

How the results depend on the processing

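Settings were fixed before the data were examined, except collapsing and thinning. No result reversed a called direction. The cause of a change was not tested unless the setting itself shows it.

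Calls for APAP against Control, 3 in the main test, became 7 with RLE, 8 with library totals, 7 with upper-quartile factors (6 higher, 1 lower), 9 without a filter, 0 at a mean of at least 10 CPM (fewer miRNAs tested, and 2 of the 3 removed by abundance), 13 with DESeq2, 8 with limma on log2(TPM + 1), 7 with only the 2 groups, and 0 after thinning, with 0 to 9 when a library was left out. For dmPGE2+APAP against APAP, 1 call became 9 without a filter, 8 with DESeq2 and 0 with only the 2 groups (0 to 5 with a library left out). For dmPGE2+APAP against Control, 1 became 2 with RLE, library totals, no filter or DESeq2, and 0 at 10 CPM, with limma-voom or after thinning (1 to 2 with a library left out). At 10 CPM and after thinning the filters removed miR-503-5p and miR-6481, so these were not tested there.

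Shifted lists went from 4 to 0 with an estimated correlation and 2 after thinning in APAP against Control (3 to 5 with a library left out), from 3 to 0 and 1 in dmPGE2+APAP against APAP (2 to 4), and from 0 to 1 with library totals in dmPGE2+APAP against Control (0 to 1). Opposite calls, 0, became 5 at an adjusted p of 0.1, 1 with RLE or library totals and 5 with DESeq2 (0 to 4 with a library left out). The 5 at 0.1 include rows that count nearly the same miR-486 reads. Shared calls, 1, became 2 at 0.1, with RLE, library totals or DESeq2, and 0 at 10 CPM (0 to 2). Shares of miR-122-5p became 24.8%, 23.6% and 25.4% with shared rows collapsed.

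With the replicate number as a block the calls were 0, 2 and 1 for the 3 comparisons, with 0 shared calls, 0 opposite calls and 4, 3 and 0 lists. Replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated between -0.248 and 0.172, above 0.1 in 2 of 9 pairs. Over 22 alternatives miR-451a in dmPGE2+APAP against APAP kept log2 values of -1.57 to -1.05 and passed in 19 of them (edgeR or other adjusted p 1.00e-05 to 0.0964), and miR-21a-3p in APAP against Control 1.63 to 2.66, passing in 15 (3.20e-07 to 0.112). Depth limits the low miRNAs, as thinning to 1038799 reads ended every call but that of miR-451a.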

Other observations

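Families tested here were chosen after the data were seen. Of the 9 tested miRNAs of the miR-23, miR-27 and miR-24 clusters, 9 had values above 0 in dmPGE2+APAP against Control (median log2 0.35, adjusted camera p 0.00297), and adjusted p = 0.363 with an estimated correlation. Against Control, APAP alone gave a median of 0.19 (adjusted p 0.0772) and 6 of 9 values above 0. The cluster of miR-322 and miR-503 had a median of -0.07 after APAP, with 4 of 9 values above 0, and did not pass (camera direction up, adjusted camera p 0.622). Whether miR-503-5p differed from the other members was not tested. The miR-181 family, the miR-15 and miR-16 family and the family that includes miR-10 and miR-99 had medians of -0.28, 0.02 and -0.02 after APAP, and none passed.

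Muscle miRNAs varied within Control. miR-1a-3p held 2544 CPM in Control replicate 1, 1010.3 in replicate 2 and 452 in replicate 3, and miR-133a-3p held 54.0, 31.8 and 16 CPM. The lymphocyte miRNA miR-150-5p had 13 reads in Control replicate 1 against 180 and 210 in the other Control libraries. miR-6481 was read 0, 0 and 3 times in Control, 49, 25 and 19 times in APAP, and 33, 29 and 159 times in dmPGE2+APAP.

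In dmPGE2+APAP replicate 2, the shallowest library, 10 miRNAs stood at least 2-fold above every other library, with the near-identical rows of miR-129-5p and miR-129b-3p counted once, against 0 to 2 in each of the others. The largest gaps were those of miR-205-5p at 80 reads (1 to 27 elsewhere), miR-200c-3p at 173 (81 to 211) and miR-9-5p at 34 (28 to 61). Carried-over reads at a similar number per library and other tissue in this library alone predict different slopes of reads on depth over the other 8 libraries. The median slope was 0.676 (log2 per log2), with a bootstrap 95% interval of -0.00252 to 0.912 that spans the dividing bound of 0.5, so the explanations cannot be told apart with 10 miRNAs of this low count. Counting error at shallow depth does not account for their number: 1000 draws at this library's depth, from fits to the other 8 and chosen after the count was seen, gave a mean of 1.20 such miRNAs and at most 6.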
